A study of Mus musculus with 36 samples.

How the data were processed

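The series measured gene expression in germ cells and supporting cells sorted from fetal mouse gonads. Supporting cells are the somatic lineage that becomes Sertoli cells in the testis and granulosa cells in the ovary. Per the labels' protocols, gonads of each sex were pooled, dissociated with trypsin and stained with DAPI, and fluorescent cells were collected by flow sorting. Germ cells carried an Oct4 reporter at every stage. Supporting cells carried an Sry-EGFP reporter on a CD-1 background in XX gonads at every stage and in XY gonads at 11.5 days post coitum (dpc), and a Sox9 reporter on a C57BL/6 background in XY gonads at 12.5 and 13.5 dpc. The sexes of the supporting cells at 12.5 and 13.5 dpc, the stages of the XY supporting cells and the change of their sex difference therefore coincide with the reporter line and strain. Interstitial and stromal cells, which the series also names, were not analysed here.

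RNA was hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The values used here are log2 expression per probe set as deposited by the authors, made with RMA per the submitters' processing notes, with the version not given in the sources used here. RMA corrects background, normalises between arrays and summarises the probes of a probe set. The deposited table held 35557 probe sets on 36 arrays, with values from 3.17 to 15.05. Array medians over the tested genes lay between 6.54 and 7.01, so the arrays still differed in level. No 2 arrays held identical values, and the lowest and highest correlations between arrays of a group were 0.895 and 0.995. The number of arrays, 3 in each of 12 groups, limits the precision of every value. No scan date or slide was given in the sources used here, so no batch was modelled. The labels do not say that the 3 arrays of a group came from separate litters or pools, so p-values measure only the spread between these samples, which may be technical.

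The spacing of the values within each array showed a step that no label describes. In 35 arrays the probe sets fell into 3 interleaved sets of table rows, and in 1 array into 2, each set on its own linear scale, with 3 values in no set. There were 107 such row sets, with slopes from 1.0099 to 1.059. The medians of the highest and lowest set of an array lay 0.02 to 0.75 apart on the log2 scale, with a median gap of 0.3, and the gap was above 0.5 in 10 arrays. Between 2 arrays, 33.4 to 99.9% of the probe sets fell into matching sets, with a median of 40.2%. The deposited values were kept for every main result. An alternative divided each set by its slope and moved every set of every array to a single median (row sets aligned), which also centres the arrays. What made the sets is not given in the sources used here, so small differences on the log2 scale hold only up to this step.

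A GEO platform annotation listed 23410 of the probe sets. Of these, 21789 had 1 gene symbol and 1621 had several, and the other 12147 probe sets were unnamed here. For 21698 of the probe sets with 1 symbol the gene identifier matched the reference gene table (assembly GRCm38.p6, used for names and chromosomes), and 0 symbols changed. Probe sets with several symbols or none were left out. For the 999 genes with several probe sets, the probe set with the highest mean over all arrays stood for the gene. This left 19938 genes, 739 of them on the X chromosome and 9 on the Y chromosome. No filter on dim genes was applied.

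Genes were tested with limma 3.58.1 in R 4.3.3. All 36 arrays entered a single linear model with 12 group means and 24 residual degrees of freedom, followed by empirical Bayes moderation, and the 13 comparisons were contrasts of these means. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 19938 genes within a comparison, and genes with an adjusted p under 0.05 were counted as changed. A standard error (SE) is the moderated error of the contrast. It rests on the spread of all 36 arrays around their group means, not only on that of the arrays compared. The comparisons were XY minus XX in each cell type and stage, 13.5 minus 11.5 dpc in each cell type and sex, germ minus supporting cells averaged over their 6 groups, and the change of the XY minus XX difference from 11.5 to 13.5 dpc in each cell type. Table handling and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

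There were 24 gene lists, fixed from textbook knowledge of the fetal gonad. They were germ cell identity, pluripotency, meiosis, male germ cell differentiation, the piRNA pathway, the retinoic acid pathway, Sertoli cell, pregranulosa cell, WNT targets, BMP targets, basement membrane, steroidogenic cell, interstitial or stromal cell, endothelial cell, macrophage, erythroid cell, mesonephric and epithelial cell, mitotic cell cycle, cyclin-dependent kinase inhibitors with other genes that hold the cell cycle, imprinted genes, dissociation stress, Y-linked, X inactivation and escape, and candidates for variation between strains. Some genes stand in several lists. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with the correlation estimated for each list; limma's fry was also run and is not reported. Members past the threshold were counted over all genes and adjusted over the list alone. The X-linked genes were tested likewise in the 6 sex comparisons.

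The groups, tests, lists, named genes and most alternatives were chosen before the data were examined. The named genes of a comparison were the 10 largest rises and the 10 largest falls among changed genes whose groups of arrays did not overlap (for the changes of the sex difference, among all changed genes). To these were added up to 4 changed members of each list, with any changed member that went against most others of its list, and always Pou5f1, Sry, Sox9, Xist and the Y-linked genes. Only part of the named genes is printed. The aligned row sets, the removal of the array labelled germ XX 12.5 dpc replicate 3 from every fit, and both together were chosen after seeing the data. The other alternatives were quantile normalisation over all arrays, centring each array on its median, leaving out genes whose highest group mean was at or below 6.37 (the 40th percentile of all values, which left 13800 genes), the mean over a gene's probe sets, a fit of only the arrays compared, a trended and robust prior, array weights, the replicate number as a block, autosomal genes only (sex comparisons), a further threshold of 2-fold or of an adjusted p under 0.01, X-linked genes without the X inactivation list, and leaving out each array in turn.

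The model was tested on simulated data for 19938 genes. For XY minus XX germ cells at 11.5 dpc it recovered 80 of 100 genes changed by 2-fold and 100 of 100 changed by 4-fold, with 7 false calls. For the XX germ cell stages it recovered 77 of 100 at 2-fold, with 18 false calls, and for germ minus supporting cells 100 of 100 at 2-fold, with 7. For the change of the germ cell sex difference it recovered 23 of 100 at 2-fold and 96 of 100 at 4-fold, with 4 false calls. In a simulation for germ cells at 11.5 dpc, the 1 list that was moved was called and 0 of the others were. The genes of these simulations varied independently, without row sets or differences in array level. They therefore do not test false calls that arise from correlated genes. The search for row sets found all 3 simulated sets in an array with 3 and a single set in an array with 1.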

Results

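Gene expression was measured on 36 arrays of cells sorted from fetal mouse gonads, with 3 arrays in each of 12 groups. The groups were germ cells and supporting cells of XX and XY gonads at 11.5, 12.5 and 13.5 days post coitum (dpc). Over these days supporting cells commit to a Sertoli or granulosa fate, ovarian germ cells enter meiosis and testicular germ cells stop dividing. Array medians lay between 6.54 and 7.01 on the log2 scale, and 3 arrays per group limit the precision of every value. Differences are given in log2 with the standard error (SE), and adjusted p-values (padj) of single genes are adjusted over the 19938 genes of a comparison. For gene lists, padj is that of camera with its preset correlation, adjusted over the lists, followed by the value with an estimated correlation wherever the call was lost with it.

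The Y-linked gene Eif2s3y, which encodes a translation initiation factor, stood at 8.82 or higher in every XY array and at 5.72 or lower in every XX array. The median of 16 germ cell identity genes was 9.04 to 9.78 in 17 germ cell arrays and at most 6.73 in the 18 supporting cell arrays. In the array labelled germ XX 12.5 dpc replicate 3 it was 6.19. The RNA helicase gene Ddx4, which marks germ cells, was at 5.04 in this array and at 10.46 or higher in the other germ cell arrays. Pou5f1, the pluripotency factor that drives the Oct4 reporter, was at 5.07 against 9.51 or higher. Markers of stromal cells were high in it, with the transcription factor genes Nr2f2 at 10.46 and Tcf21 at 10.82, the growth factor receptor gene Pdgfra at 10.59 and the matrix gene Dcn at 10.11. In supporting cell arrays Tcf21 and Dcn reached at most 7.39 and 7.09. The somatic gonad factors Wt1 and Gata4 were at 11.18 and 9.79, within the range of supporting cells, and the XX supporting cell genes Fst and Bmp2 at 10.81 and 10.39. Xist, the RNA that coats the inactive X chromosome, was at 11.02, against 8.28 or lower in the other germ cell arrays and up to 11.7 in supporting cells. The array kept its label in all main results, and values without it are given for part of the results, mainly for germ cells at 12.5 dpc. All arrays share a single estimate of spread per gene, so it also enters the errors of comparisons that do not hold it. Where it lies far from the other arrays of its group, as for Fst (10.81 against 6.76 and 7.19), it widens those errors and raises the p-values.

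**Figure D1:**
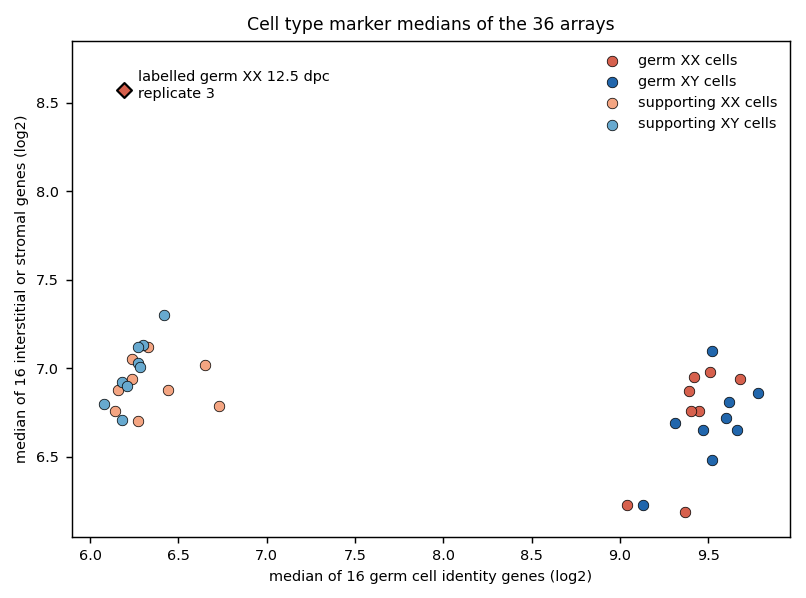
Median log2 level of 16 germ cell identity genes (horizontal) and 16 interstitial or stromal genes (vertical) in each of the 36 arrays, by cell type and sex. The diamond marks the array labelled germ XX 12.5 dpc replicate 3.

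Germ cells differed from supporting cells in 8947 genes, 5572 higher and 3375 lower (18 against 18 arrays). The germ cell arrays include the one that stood apart, as do the differences below. Without it 9410 genes passed, 5796 higher and 3614 lower. Among the genes higher in germ cells were Dppa5a (5.82, SE 0.34, padj = 6.94e-17), a pluripotency gene, Ddx4 (5.52, SE 0.31, padj = 1.69e-17) and the RNA-binding gene Dazl (5.12, SE 0.29, padj = 2.69e-17), needed for germ cell development. Pou5f1 was higher by 5.16 (SE 0.28, padj = 6.3e-18). Lower in germ cells were Kitl (-4.54, SE 0.25, padj = 1.75e-17), the ligand by which somatic cells sustain germ cells, the gonadal transcription factor Gata4 (-2.76, SE 0.15, padj = 1.04e-17) and the Sertoli cell factor Sox9 (-2.23, SE 0.09, padj = 7.8e-21). The basement membrane genes mostly lay lower, yet Fn1, the gene of fibronectin, was higher by 3.75 (SE 0.10, padj = 5.97e-26).

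In germ cells all 16 germ cell identity genes were higher (16 adjusted over the list alone; padj = 6.96e-14, with adjusted p = 0.113 with an estimated correlation). Of 15 pluripotency genes 13 were higher and Klf4 (-0.95) was lower (13 and 1 adjusted over the list alone; padj = 8.86e-09, adjusted p = 0.124 with an estimated correlation). The meiosis list had 22 of 25 genes higher (22 adjusted over the list alone; padj = 6.96e-14, adjusted p = 0.113 with an estimated correlation), among them the chromosome axis gene Hormad1 (4.69) and the synaptonemal gene Sycp3 (4.06). The piRNA list had 15 of 17 higher (15 adjusted over the list alone; padj = 8.86e-09, adjusted p = 0.113 with an estimated correlation). All 23 mitotic cell cycle genes were higher (23 adjusted over the list alone; padj = 2.27e-21, and 0.0245 with an estimated correlation), with the spindle checkpoint gene Bub1 at 3.76 (SE 0.16). Of 27 Sertoli cell genes 25 were lower and Erbb3 (0.35) was higher (25 and 2 adjusted over the list alone; padj = 5.93e-20, and 0.00269 with an estimated correlation). The pregranulosa list had 12 of 21 lower and 2 higher (13 and 3 adjusted over the list alone; padj = 3.37e-06, adjusted p = 0.162 with an estimated correlation). For the steroidogenic list 6 of 11 were lower (6 adjusted over the list alone; padj = 0.000398, adjusted p = 0.113 with an estimated correlation), and for the basement membrane list 11 of 15 were lower and 2 higher (11 and 2 adjusted over the list alone; padj = 0.00173, adjusted p = 0.162 with an estimated correlation). Of 16 interstitial or stromal genes 4 were lower and 1 higher (4 and 0 adjusted over the list alone; padj = 0.408), with a median of 0.04 and a mean of -0.09. The germ cell side includes the array that stood apart, whose stromal median was 8.57, against at most 7.1 in the other germ cell arrays. List results without it are not given here for this comparison. The count of changed genes was 11786 with row sets aligned (5851 higher, 5935 lower), and with quantile normalisation 4204 were higher and 5076 lower. Germ and supporting cells came from different reporter lines.

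At 11.5 dpc the sexes differed in 5 genes in germ cells, all on the Y chromosome and higher in XY (3 against 3 arrays). They were Eif2s3y (5.20, SE 0.23, padj = 1.9e-18), the ubiquitin-activating enzyme gene Uba1y (4.10, SE 0.19, padj = 4.14e-18), the histone demethylase genes Kdm5d (2.80, SE 0.21, padj = 2.25e-11) and Uty (2.73, SE 0.24, padj = 1.03e-09), and the zinc finger gene Zfy1 (2.68, SE 0.23, padj = 4.6e-10). Xist was not past the test (-0.49, SE 0.51, padj = 1.0), with a mean level of 7.05 in XX and 6.56 in XY germ cells. No autosomal gene passed in limma (333 at an unadjusted p under 0.05, 2 past the test with row sets aligned), and 385 of all genes had an unadjusted p under 0.05. Of the 24 lists, the 3 Y-linked genes were all higher (3 adjusted over the list alone; padj = 1.25e-60, and 1.28e-11 with an estimated correlation). The 5 genes of X inactivation and escape lay lower as a list (0 past limma, 3 at an unadjusted p under 0.05, 3 lower adjusted over the list alone, 1 past the test with row sets aligned; padj = 8.07e-09, and 0.000781 with an estimated correlation). The count was 9 with row sets aligned (6 higher, 3 lower), 15 in a fit of only these 6 arrays, and 6 with arrays centred (5 higher, 1 lower).

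At 12.5 dpc 775 genes differed between XY and XX germ cells, 252 higher and 523 lower in XY, with the array that stood apart among the 3 XX arrays. Higher in XY were Tdgf1 (3.59, SE 0.36, padj = 2.52e-08), a co-receptor for NODAL, the glutathione transferase gene Mgst2 (3.56, SE 0.37, padj = 4.13e-08), and the transcription factors Etv1 (2.52, SE 0.27, padj = 6.82e-08) and Lhx1 (1.92, SE 0.25, padj = 5.47e-06). Without that array these were at 2.87, 3.54, 2.77 and 1.63. Lower in XY were Id2 (-2.71, SE 0.39, padj = 4.08e-05) and Id1 (-1.57, SE 0.25, padj = 0.000197), targets of BMP signalling, the kinase gene Nrk (-2.42, SE 0.30, padj = 2.92e-06) and Crabp2 (-1.41, SE 0.29, padj = 0.00392), which binds retinoic acid. Without the array these were at -2.09, -1.36, -2.04 and -1.29. Stra8, which retinoic acid induces before meiosis, was chosen after its values were seen: it did not pass (-0.953, SE 0.345, padj = 0.112), and did without the array (-1.76, SE 0.24, padj = 1.73e-06). Rec8, a meiotic cohesin, was lower (-0.91, SE 0.25, padj = 0.0327), and the recombination gene Tex11 was higher by 2.15 (SE 0.34, padj = 0.000187). The X-linked demethylase gene Kdm6a was lower (-1.56, SE 0.24, padj = 0.000182), and so was Xist (-2.89, SE 0.51, padj = 0.000933), at -1.70 (padj = 0.00127) without the array. For Rec8, Tex11 and Kdm6a values without the array are not given here, so how far it shaped them stays open. The meiosis gene Sycp3 was at 5.9 in it, against 8.26 or higher in the other germ cell arrays.

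Some of these calls went with the array. The stromal genes Nr2f2 (-1.61, SE 0.46, padj = 0.0392), Dcn (-2.09, SE 0.41, padj = 0.00276) and Postn (-1.30, SE 0.35, padj = 0.0306) were lower in XY with it, and without it Nr2f2 was at -0.54 (padj = 0.404), while Dcn still passed (-1.24, SE 0.31, padj = 0.0184). Without it Postn and the germ cell genes Dppa3 (2.41, SE 0.67, padj = 0.0355) and Dppa5a (3.0, SE 0.84, padj = 0.037) were no longer past the test. Of 16 germ cell identity genes 1 was higher (5 adjusted over the list alone; padj = 1.93e-06, adjusted p = 0.263 with an estimated correlation), against padj = 0.991 without the array. The meiosis list had 2 of 25 higher and 1 lower (2 and 1 adjusted over the list alone; up, padj = 0.0348, adjusted p = 0.582 with an estimated correlation), and without the array 1 higher and 4 lower (down, padj = 0.00107, adjusted p = 0.382 with an estimated correlation). The meiosis call was also lost without XY replicate 2 (padj = 0.0707), without XY replicate 3 (padj = 0.109), with arrays centred (padj = 0.159) and with row sets aligned (padj = 0.167). Pluripotency had 4 of 15 higher (8 adjusted over the list alone; padj = 8e-07, adjusted p = 0.204 with an estimated correlation), and padj = 0.178 without the array. The piRNA list had 1 of 17 higher (7 adjusted over the list alone; padj = 2.72e-05, adjusted p = 0.239 with an estimated correlation). Without the array 0 of the piRNA genes passed limma (4 at an unadjusted p under 0.05; padj = 0.762). Of 16 interstitial or stromal genes 3 were lower and 1 higher (6 and 1 adjusted over the list alone; padj = 0.001, adjusted p = 0.363 with an estimated correlation), with padj = 0.996 without the array. Pregranulosa genes were lower in 3 of 21 (6 adjusted over the list alone; padj = 0.000351, adjusted p = 0.341 with an estimated correlation), with padj = 0.996 without it. Steroidogenic genes were lower in 1 of 11, Fdx1 at -0.74 (2 adjusted over the list alone; padj = 0.00805, adjusted p = 0.239 with an estimated correlation), with padj = 0.113 without the array and 0.0583 with row sets aligned. Basement membrane genes were lower in 1 of 15, Lama1 at -1.11 (1 adjusted over the list alone; padj = 0.0156, adjusted p = 0.341 with an estimated correlation), with padj = 0.395 without the array. The mitotic cell cycle list lay higher with 0 of 23 past limma (6 at an unadjusted p under 0.05, 0 adjusted over the list alone, 1 past the test with row sets aligned; padj = 0.00205, adjusted p = 0.394 with an estimated correlation), with padj = 0.996 without the array.

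Male germ cell differentiation genes at 12.5 dpc were higher in 5 of 19 and lower in 1, Sox12 at -0.95 (8 and 2 adjusted over the list alone; padj = 8.72e-05, adjusted p = 0.183 with an estimated correlation), and without the array 4 were higher (padj = 0.0208, adjusted p = 0.484 with an estimated correlation). BMP targets were lower in 4 of 12 (4 adjusted over the list alone; padj = 0.000206, adjusted p = 0.183 with an estimated correlation), and in 3 without the array (padj = 0.00175, adjusted p = 0.382 with an estimated correlation). WNT targets were lower in 2 of 13 (5 adjusted over the list alone; padj = 0.000262, adjusted p = 0.141 with an estimated correlation). Without the array 0 of the WNT targets passed limma (4 at an unadjusted p under 0.05; padj = 0.0116, adjusted p = 0.382 with an estimated correlation). The retinoic acid list had 2 of 17 lower, Crabp2 and the receptor gene Rxra (5 adjusted over the list alone; padj = 0.183). Without the array it had 1 higher and 3 lower (padj = 0.991, median 0.11), and with row sets aligned and all arrays it passed downward (padj = 0.00289). Camera with an estimated correlation was also run with row sets aligned and the array left out. Adjusted p was then 0.0263 for male germ cell differentiation, 0.0435 for BMP targets and 0.00977 for WNT targets. It was 0.0563 for meiosis and 0.493 for the retinoic acid list. The count fell to 358 without the array labelled XX replicate 3, 439 without XY replicate 1, 179 without XY replicate 2 and 431 without XY replicate 3, and rose to 1936 without XX replicate 1 and 1266 without XX replicate 2. It was 8 in a fit of only these 6 arrays and 111 with array weights. With row sets aligned 756 genes passed (373 higher, 383 lower), 349 of them shared, and with arrays centred 818 were higher and 703 lower.

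**Figure D2:**
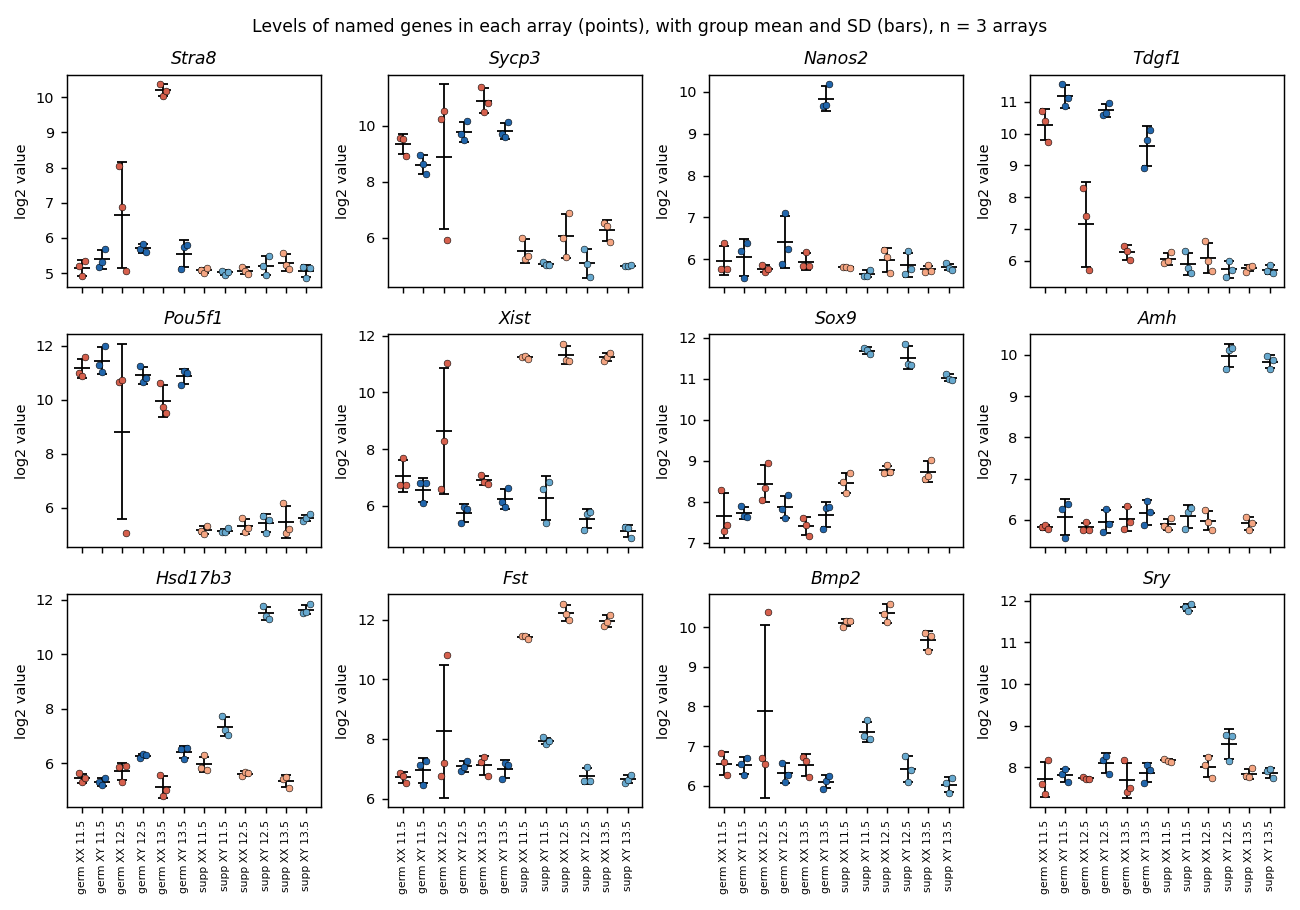
Log2 level of 12 genes in germ and supporting cells of each sex and stage. Points are arrays; bars give the mean and SD (n = 3 arrays per group). The array labelled germ XX 12.5 dpc replicate 3 is included.

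At 13.5 dpc 1275 genes differed between XY and XX germ cells, 717 higher and 558 lower in XY (3 against 3 arrays). Stra8 was lower (-4.64, SE 0.34, padj = 3.74e-12), with a mean level of 10.20 in XX and 5.56 in XY. Meiotic genes followed, with Meioc (-4.55, SE 0.37, padj = 4.03e-11), which keeps germ cells in meiotic prophase, Meiob (-3.98, SE 0.42, padj = 2.39e-08) and Spata22 (-3.48, SE 0.21, padj = 8.57e-15), which act in recombination, and Prdm9 (-2.85, SE 0.27, padj = 1.19e-09), which places its breaks. Nanos2, which directs the male germ cell program, was higher in XY by 3.89 (SE 0.23, padj = 8.57e-15), with levels of 9.84 and 5.95. Tdgf1 (3.36, SE 0.36, padj = 3.21e-08), the homeobox gene Hesx1 (3.51, SE 0.24, padj = 2.91e-13) and Morc1 (2.67, SE 0.30, padj = 1.12e-07), needed for transposon silencing, were also higher. Id2 (-2.80, SE 0.39, padj = 6.14e-06) and Id3 (-2.15, SE 0.25, padj = 1.28e-07) were lower, and so was the imprinted gene Phlda2 (-3.58, SE 0.42, padj = 2.33e-07).

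The meiosis list at 13.5 dpc had 11 of 25 genes lower in XY (18 adjusted over the list alone; padj = 1.21e-24, and 0.0242 with an estimated correlation), and male germ cell differentiation had 9 of 19 higher (10 adjusted over the list alone; padj = 6.46e-14, and 0.00911 with an estimated correlation). Pluripotency had 4 of 15 higher (5 adjusted over the list alone; padj = 0.000134, adjusted p = 0.456 with an estimated correlation), among them Tdgf1 and Utf1 (1.56). BMP targets had 4 of 12 lower and Hey1 (0.98) higher (5 and 1 adjusted over the list alone; padj = 6.06e-06, adjusted p = 0.0829 with an estimated correlation), and WNT targets 3 of 13 lower (4 adjusted over the list alone; padj = 0.00497, adjusted p = 0.254 with an estimated correlation). The piRNA list had 3 of 17 higher (3 adjusted over the list alone; padj = 0.0581). It passed with the replicate number as a block (padj = 0.0364) and without XX replicate 3 (padj = 0.033), XY replicate 2 (padj = 0.0021) or the array labelled germ XX 12.5 dpc replicate 3 (padj = 0.0172). The retinoic acid list had 1 higher, Aldh1a1 (1.77), and 2 lower (1 and 2 adjusted over the list alone; padj = 0.723, median 0.03, mean 0.01, test downward). The count was 696 without XX replicate 3, 807 without XY replicate 3 and 1914 without XY replicate 1. It was 2671 with row sets aligned and 6461 with array weights, and with quantile normalisation 785 were higher and 832 lower. The genes shared with 12.5 dpc were 110 higher and 99 lower, against 9.1 and 14.6 if the lists were independent. The calls at 12.5 dpc include the array labelled germ XX 12.5 dpc replicate 3, without which 85 were higher and 273 lower there.

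Supporting cells at 11.5 dpc differed between the sexes in 392 genes, 212 higher and 180 lower in XY (3 against 3 arrays, 1 reporter line). The testis-determining gene Sry was higher in XY by 3.67 (SE 0.21, padj = 1.43e-15), a lower bound since XX cells were at background. Its target Sox9 was higher by 3.23 (SE 0.23, padj = 7.47e-13) and the growth factor gene Fgf9, which maintains Sox9, by 3.65 (SE 0.18, padj = 3.77e-17). The metabolic coactivator Ppargc1a (3.90, SE 0.25, padj = 5.76e-14), the transcription factor Etv5 (3.64, SE 0.35, padj = 3.21e-09) and the laminin gene Lama4 (3.50, SE 0.31, padj = 5.53e-10) were higher as well. Lower in XY were Fst (-3.49, SE 0.47, padj = 5.99e-06), which binds activin in the ovary, the signalling gene Bmp2 (-2.76, SE 0.46, padj = 0.000225), the WNT effector Lef1 (-1.55, SE 0.21, padj = 8.57e-06) and the cystine transporter gene Slc7a11 (-2.96, SE 0.21, padj = 7.47e-13). Xist was lower (-4.96, SE 0.51, padj = 1.53e-08), with a level of 11.24 in XX.

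Of 27 Sertoli cell genes 8 were higher in XY supporting cells at 11.5 dpc (9 adjusted over the list alone; padj = 7.08e-32, and 5.75e-05 with an estimated correlation). Of 21 pregranulosa genes 6 were lower, and Lgr5 (1.36), also on the WNT target list, was higher (9 and 1 adjusted over the list alone; padj = 4.21e-10, adjusted p = 0.088 with an estimated correlation). Mitotic cell cycle genes were higher in 3 of 23 (12 adjusted over the list alone; padj = 2.77e-18, and 0.0258 with an estimated correlation), among them the kinesin gene Kif11 (1.52, SE 0.34). Basement membrane genes were higher in 3 of 15 (3 adjusted over the list alone; padj = 3.19e-06, adjusted p = 0.0601 with an estimated correlation). Interstitial or stromal genes included Pdgfra (1.80, SE 0.50) and Ptch1 (0.92, SE 0.23), 2 of 16 higher (2 adjusted over the list alone; padj = 0.61, median -0.09, mean 0.04). The count was 255 without XX replicate 2, 249 without XY replicate 3 and 663 without the array labelled germ XX 12.5 dpc replicate 3. With row sets aligned it was 1124 (746 higher, 378 lower), with quantile normalisation 378 were higher and 199 lower, and with array weights it was 2162.

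At 12.5 dpc 2119 genes differed between XY and XX supporting cells, 1383 higher and 736 lower in XY (3 against 3 arrays), with sex coinciding with reporter line and strain. The androgen-forming enzyme gene Hsd17b3 was higher by 5.88 (SE 0.20, padj = 5.12e-22), Amh, the hormone that removes the Müllerian duct, by 4.0 (SE 0.21, padj = 8.61e-17) and Sox9 by 2.75 (SE 0.23, padj = 1.1e-11). The calcium-binding gene Tesc (4.14, SE 0.24, padj = 1.37e-15) and Cyp26b1 (1.86, SE 0.22, padj = 4.25e-08), which degrades retinoic acid, were higher too. The spindle genes Tpx2 (3.88, SE 0.26, padj = 7.02e-14) and Kif11 (3.69, SE 0.34, padj = 1.39e-10) were higher, and Cdkn1b, which restrains the cell cycle, was lower (-2.95, SE 0.57, padj = 0.000245). Lower in XY were Fst (-5.48, SE 0.47, padj = 3.1e-11), the gonadal factor Lhx9 (-4.08, SE 0.52, padj = 1.92e-07), Bmp2 (-3.93, SE 0.46, padj = 4.38e-08) and Dhrs3 (-2.51, SE 0.38, padj = 6.62e-06), which reduces retinal. Sry did not pass (0.54, SE 0.21, padj = 0.0929).

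Sertoli cell genes at 12.5 dpc were higher in 24 of 27 (25 adjusted over the list alone; padj = 7.15e-44, and 6.02e-06 with an estimated correlation), and pregranulosa genes lower in 11 of 21 (12 adjusted over the list alone; padj = 5.8e-16, and 0.027 with an estimated correlation). Mitotic cell cycle genes were higher in 20 of 23 (21 adjusted over the list alone; padj = 2.23e-42, and 0.000457 with an estimated correlation). Basement membrane genes were higher in 5 of 15 (5 adjusted over the list alone; padj = 0.000207, adjusted p = 0.146 with an estimated correlation). BMP targets were lower in 3 of 12 and Smad7 (0.79) was higher (3 and 1 adjusted over the list alone; padj = 0.0125, adjusted p = 0.354 with an estimated correlation). Without XY replicate 3 the BMP list had padj = 0.088. The steroidogenic list had 3 of 11 higher (3 higher and 1 lower adjusted over the list alone; padj = 0.133, and 0.0494 without XY replicate 1), the stromal list 2 higher and 1 lower (2 and 2 adjusted over the list alone), and the erythroid list 2 of 7 higher, Hba-x (1.05) and Alas2 (0.70) (3 adjusted over the list alone; padj = 0.233). In the direction of the difference at 12.5 dpc, 173 genes were also higher and 110 also lower at 11.5 dpc, within 1 line, against 14.7 and 6.6 if the lists were independent. The count was 4750 with row sets aligned.

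The sex difference of supporting cells at 13.5 dpc held 1947 genes, 1188 higher and 759 lower in XY (3 against 3 arrays), again with reporter line and strain. Hsd17b3 was higher by 6.30 (SE 0.20, padj = 4.86e-23), Amh by 3.92 (SE 0.21, padj = 1.8e-16) and Ptgds, the prostaglandin D synthase gene that promotes Sox9 activity, by 3.52 (SE 0.20, padj = 8.44e-16). Cyp17a1 (1.94, SE 0.23, padj = 8.23e-08) and Cyp11a1 (1.65, SE 0.24, padj = 2.52e-06), which act in steroid synthesis, and the cholesterol carrier gene Star (1.36, SE 0.21, padj = 8.76e-06) were higher too. Lower were Fst (-5.30, SE 0.47, padj = 6.57e-11), the G protein gene Gng13 (-3.92, SE 0.29, padj = 1.19e-12), the WNT target Axin2 (-1.97, SE 0.20, padj = 2.02e-09) and Aldh1a2, which makes retinoic acid (-1.69, SE 0.45, padj = 0.00897). Sertoli cell genes were higher in 23 of 27 (23 adjusted over the list alone; padj = 1.69e-45, and 3.44e-06 with an estimated correlation), and pregranulosa genes lower in 11 of 21 (14 lower and 1 higher adjusted over the list alone; padj = 1.99e-18, and 0.0149 with an estimated correlation). Mitotic cell cycle genes were higher in 20 of 23 (21 adjusted over the list alone; padj = 1.61e-46, and 0.00024 with an estimated correlation).

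Steroidogenic genes at 13.5 dpc, markers of another gonadal cell type, were higher in 4 of 11 (5 adjusted over the list alone; padj = 0.00256, adjusted p = 0.188 with an estimated correlation). WNT targets were lower in 4 of 13 (5 lower and 1 higher adjusted over the list alone; padj = 0.0261, adjusted p = 0.306 with an estimated correlation). The WNT list had padj = 0.0539 without XX replicate 1 and 0.0509 without XY replicate 2. Basement membrane genes were higher in 2 of 15 (4 adjusted over the list alone; padj = 0.00139, adjusted p = 0.195 with an estimated correlation). The sex differences at 12.5 and 13.5 dpc shared 916 higher and 485 lower genes, against 82.4 and 28 if independent. The count was 4324 with row sets aligned, 4275 in a fit of only these 6 arrays and 6066 with array weights.

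From 11.5 to 13.5 dpc 2390 genes changed in XX germ cells, 927 rising and 1463 falling (3 against 3 arrays). Stra8 rose by 5.05 (SE 0.34, padj = 1.05e-12), Meioc by 4.75 (SE 0.37, padj = 1.74e-11), and the synaptonemal complex genes Tex12 by 4.36 (SE 0.54, padj = 4.37e-07) and Sycp1 by 4.17 (SE 0.38, padj = 9.47e-10). The pluripotency genes Tdgf1 (-4.02, SE 0.36, padj = 5.58e-10), Zfp42 (-2.37, SE 0.39, padj = 5.75e-05) and Nanog (-2.25, SE 0.37, padj = 4.99e-05) fell, as did Nanos3, which protects migrating germ cells (-1.87, SE 0.28, padj = 1.04e-05). Meiosis genes rose in 18 of 25 (22 adjusted over the list alone; padj = 8.69e-31, and 0.0275 with an estimated correlation). Pluripotency genes fell in 8 of 15 (10 adjusted over the list alone; padj = 2.34e-06, adjusted p = 0.522 with an estimated correlation). The piRNA list rose in 5 of 17, and Pld6 (-0.56) fell (6 and 1 adjusted over the list alone; padj = 0.000172, adjusted p = 0.665 with an estimated correlation). Of 16 germ cell identity genes 1 rose and 5 fell (1 and 5 adjusted over the list alone; padj = 0.158), and of 23 mitotic cell cycle genes 1 rose, Ccne2 at 1.38, and 6 fell (1 and 6 adjusted over the list alone; padj = 0.0564). The mitotic list passed downward with the replicate number as a block (padj = 0.0478) and with row sets aligned (padj = 0.0144). It also passed without 11.5 dpc replicate 1 (padj = 0.0435) or 3 (padj = 0.035) or 13.5 dpc replicate 2 (padj = 0.0275) or 3 (padj = 0.0166). The erythroid globin genes Hbb-y (-2.80, SE 0.86, padj = 0.0267) and Hba-x (-1.08, SE 0.32, padj = 0.0198) fell, 2 of the 7 erythroid genes. The median over all genes was -0.143, and -0.031 with row sets aligned. With quantile normalisation 1646 rose and 1316 fell. The count was 1405 without XX 13.5 dpc replicate 3 and 5203 with array weights.

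In XY germ cells 924 genes changed over the same days, 395 rising and 529 falling (3 against 3 arrays). Nanos2 rose by 3.79 (SE 0.23, padj = 7.33e-14), the zinc finger gene Bnc2 by 4.05 (SE 0.33, padj = 1.22e-10), Hesx1 by 3.64 (SE 0.24, padj = 2.46e-13) and Gtsf1, a piRNA cofactor, by 3.16 (SE 0.28, padj = 4.98e-10). Phlda2 (-3.31, SE 0.42, padj = 1.41e-06), the Notch and BMP target Hey1 (-2.08, SE 0.24, padj = 2.35e-07) and Id3 (-2.03, SE 0.25, padj = 5.59e-07) fell. The piRNA list rose in 7 of 17 (11 up and 1 down adjusted over the list alone; padj = 1.54e-16, and 0.0207 with an estimated correlation). Male germ cell differentiation genes rose in 5 of 19, and Tdgf1 fell by 1.55 (7 and 1 adjusted over the list alone; padj = 3.24e-11, and 0.0207 with an estimated correlation). BMP targets fell in 4 of 12 (5 adjusted over the list alone; padj = 7.96e-08, and 0.029 with an estimated correlation). Meiosis genes rose in 7 of 25, Sycp2 by 3.53 (7 up and 1 down adjusted over the list alone; padj = 7.96e-08, adjusted p = 0.426 with an estimated correlation). Pluripotency genes fell in 3 of 15 (4 adjusted over the list alone; padj = 0.00105, adjusted p = 0.585 with an estimated correlation), and of 23 mitotic cell cycle genes Ccne1 fell by 1.84 (3 adjusted over the list alone; padj = 0.000603, adjusted p = 0.585 with an estimated correlation). The count was 604 without XY 11.5 dpc replicate 3, 1416 without the array labelled germ XX 12.5 dpc replicate 3 and 2090 with row sets aligned. With quantile normalisation 625 rose and 557 fell.

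XX supporting cells changed in 560 genes from 11.5 to 13.5 dpc, 326 rising and 234 falling (3 against 3 arrays). The matrix gene Egfl6 rose by 3.78 (SE 0.49, padj = 1.32e-06), Gng13 by 2.98 (SE 0.29, padj = 5.25e-09), Aldh1a1, which makes retinoic acid, by 2.95 (SE 0.40, padj = 2.72e-06) and Lgr5 by 1.99 (SE 0.36, padj = 0.000344). The lipase-related gene Pnliprp2 fell by 5.48 (SE 0.34, padj = 6.04e-14) and Cyp11a1, which starts steroid synthesis, by 2.41 (SE 0.24, padj = 5.25e-09). Mitotic cell cycle genes fell in 5 of 23 (12 adjusted over the list alone; padj = 7.8e-15, adjusted p = 0.2 with an estimated correlation), with the kinetochore gene Cenpe at -1.57 (SE 0.26). Pregranulosa genes rose in 4 of 21 (4 adjusted over the list alone; padj = 0.0737, and 0.046 without 13.5 dpc replicate 1), retinoic acid genes in 4 of 17 (4 up and 2 down adjusted over the list alone; padj = 0.166, and 0.0355 without the array labelled germ XX 12.5 dpc replicate 3), and WNT targets in 3 of 13 with Bambi (-0.70) falling (3 and 1 adjusted over the list alone; padj = 0.212). Of the basement membrane list Lama1 rose by 1.12 (1 adjusted over the list alone; padj = 0.00838, adjusted p = 0.667 with an estimated correlation). Without 13.5 dpc replicate 2 this list had padj = 0.0839. The BMP target list had 2 rising and 3 falling (3 and 3 adjusted over the list alone; padj = 0.96, median -0.08, mean 0.09, test upward). The count was 366 without XX 13.5 dpc replicate 2, 1495 with row sets aligned, 1296 in a fit of only these 6 arrays and 2713 with array weights.

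XY supporting cells changed in 1188 genes, 893 rising and 295 falling (3 against 3 arrays), between an Sry line at 11.5 dpc and a Sox9 line at 13.5 dpc. Kazald1, an extracellular binding protein gene, rose by 4.88 (SE 0.22, padj = 2.64e-18), Hsd17b3 by 4.31 (SE 0.20, padj = 9.27e-18) and Amh by 3.75 (SE 0.21, padj = 7.95e-16). Sry fell by 3.96 (SE 0.21, padj = 1.15e-16), from a level of 11.83 to 7.87, and Fgf9 by 1.56 (SE 0.18, padj = 5.61e-08). XX arrays, which carry no Sry, read 7.35 to 8.25, so the level at 13.5 dpc was not above background and the fall is a lower bound. Lhx9 fell by 3.08 (SE 0.52, padj = 7.5e-05), the stromal marker Pdgfra by 2.56 (SE 0.50, padj = 0.00053), and Cyp17a1 rose by 2.24 (SE 0.23, padj = 9.63e-09). Sertoli cell genes rose in 16 of 27 and fell in 2, Sry and Fgf9 (18 and 4 adjusted over the list alone; padj = 1.15e-15, and 0.0106 with an estimated correlation). Mitotic cell cycle genes rose in 18 of 23 (19 adjusted over the list alone; padj = 2.86e-19, and 0.0378 with an estimated correlation). Pregranulosa genes fell in 2 of 21 (5 adjusted over the list alone; padj = 7.05e-07, adjusted p = 0.349 with an estimated correlation), and steroidogenic genes rose in 3 of 11 (3 adjusted over the list alone; padj = 0.0193, adjusted p = 0.387 with an estimated correlation). Without 11.5 dpc replicate 2 the steroidogenic list had padj = 0.0507. Basement membrane genes rose in 3 of 15 (3 adjusted over the list alone; padj = 0.013, adjusted p = 0.387 with an estimated correlation), and the WNT target list lay lower with 0 of 13 past limma (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, 3 past the test with row sets aligned; padj = 0.0215, adjusted p = 0.387 with an estimated correlation). The WNT list had padj = 0.0534 without 11.5 dpc replicate 1 and 0.0799 without 13.5 dpc replicate 2. The count was 714 without XY 13.5 dpc replicate 3, 2751 in a fit of only these 6 arrays and 4768 with array weights. With row sets aligned it was 3474 (2236 rising, 1238 falling), and with quantile normalisation 824 rose and 492 fell.

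The sex difference in germ cells changed from 11.5 to 13.5 dpc in 281 genes, 145 upward and 136 downward in XY (12 arrays). Stra8 moved by -4.88 (SE 0.49, padj = 3.34e-08), Meioc by -4.48 (SE 0.52, padj = 9.93e-07), Nanos2 by 3.82 (SE 0.33, padj = 1.02e-09) and Mgst2 by 4.09 (SE 0.52, padj = 5.54e-06). Id3 moved by -2.03 (SE 0.35, padj = 0.000807) and Nanos3 by 1.90 (SE 0.39, padj = 0.0061). Male germ cell differentiation genes moved upward in 8 of 19 (10 adjusted over the list alone; padj = 5.12e-12, and 0.0348 with an estimated correlation), and meiosis genes downward in 6 of 25 (10 adjusted over the list alone; padj = 1.65e-19, adjusted p = 0.088 with an estimated correlation). BMP targets moved downward in 2 of 12 (3 adjusted over the list alone; padj = 0.000388, adjusted p = 0.297 with an estimated correlation), and pluripotency genes upward in 1 of 15, Tdgf1 at 2.47 (3 adjusted over the list alone; padj = 0.00889, adjusted p = 0.968 with an estimated correlation). The pluripotency list had padj = 0.0681 without XX 13.5 dpc replicate 1 and 0.0505 with row sets aligned. The count was 185 without XX 11.5 dpc replicate 3, 159 without XX 13.5 dpc replicate 3, 179 without XY 13.5 dpc replicate 3 and 644 without the array labelled germ XX 12.5 dpc replicate 3. It was 943 with row sets aligned, 504 with quantile normalisation (226 upward, 278 downward), 581 in a fit of only these 12 arrays and 1612 with array weights.

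In supporting cells the sex difference changed in 518 genes, 345 upward and 173 downward in XY (12 arrays), with line and strain changing in the XY cells. Hsd17b3 moved by 4.92 (SE 0.29, padj = 1.95e-14), Amh by 3.73 (SE 0.29, padj = 5.56e-11), Cyp11a1 by 2.62 (SE 0.34, padj = 1.67e-06) and the cyclin gene Ccnb2 by 2.97 (SE 0.44, padj = 1.94e-05). Sry moved by -3.64 (SE 0.29, padj = 5.74e-11), a lower bound of its size since of the groups compared only XY cells at 11.5 dpc were above background. Downward too were the peptidase gene Anpep (-4.40, SE 0.49, padj = 1.52e-07) and Gng13 (-3.35, SE 0.42, padj = 1.04e-06). Sertoli cell genes moved upward in 16 of 27 and downward in 2 (19 and 3 adjusted over the list alone; padj = 5.64e-18, and 0.00248 with an estimated correlation), and mitotic cell cycle genes upward in 17 of 23 (20 adjusted over the list alone; padj = 1.08e-37, and 0.00248 with an estimated correlation). Pregranulosa genes moved downward in 4 of 21 (7 adjusted over the list alone; padj = 5.55e-10, adjusted p = 0.157 with an estimated correlation), and WNT targets in 2 of 13 (3 adjusted over the list alone; padj = 0.00122, adjusted p = 0.157 with an estimated correlation). Steroidogenic genes moved upward in 2 of 11 (2 adjusted over the list alone; padj = 0.00691, adjusted p = 0.247 with an estimated correlation). The count was 850 without the array labelled germ XX 12.5 dpc replicate 3, 1600 with row sets aligned, 1687 in a fit of only these 12 arrays and 3277 with array weights. With quantile normalisation 384 moved upward and 299 downward.

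**Figure D3:**
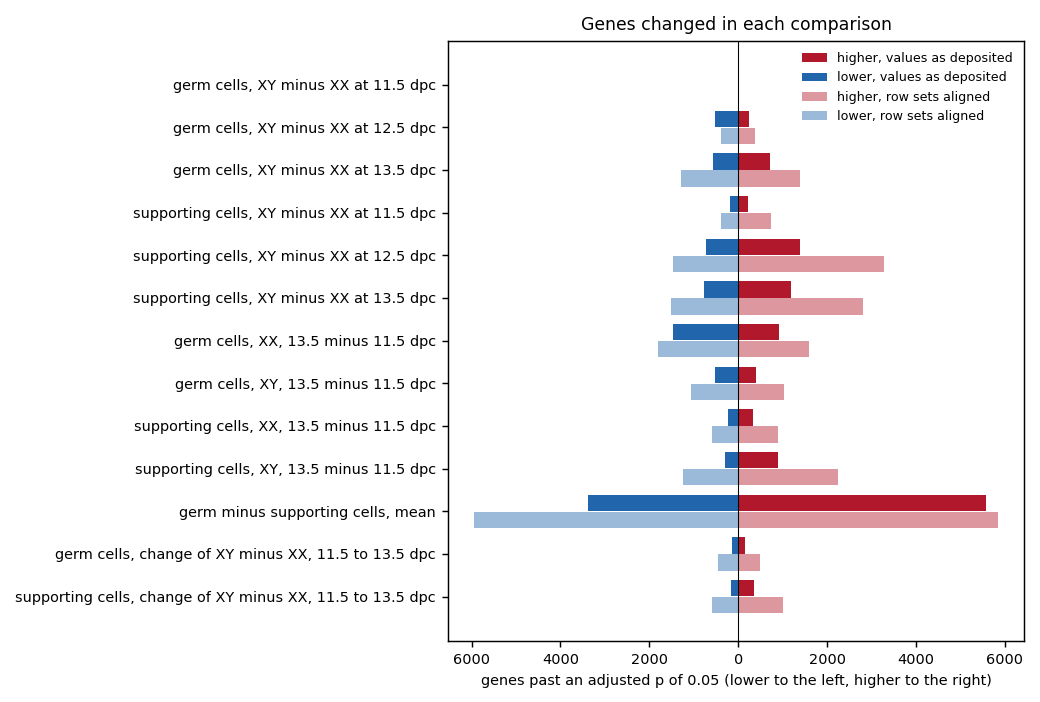
Number of genes past an adjusted p of 0.05 in each of the 13 comparisons, lower to the left and higher to the right, for the values as deposited and with row sets aligned (n = 3 arrays per group).

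The 739 X-linked genes were compared with the autosomal genes between the sexes. In germ cells the distance of their median XY minus XX difference from the autosomal median was -0.019 at 11.5 dpc (padj = 0.0806), -0.141 at 12.5 dpc (padj = 0.000513) and -0.116 at 13.5 dpc (padj = 4.4e-05), adjusted over 6 comparisons. With an estimated correlation padj was 0.927 at all 3 stages. Single X-linked genes passed as 0, 58 and 85 lower and 0, 7 and 19 higher at the 3 stages. These counts moved when 1 array was left out. At 12.5 dpc 17 were lower and 2 higher without XY replicate 2, and 110 and 21 without XX replicate 1. At 13.5 dpc 52 were lower and 33 higher without XY replicate 1, and 111 and 32 without the array labelled germ XX 12.5 dpc replicate 3. At 11.5 dpc the set passed with row sets aligned (-0.021, padj = 0.00271) and without dim genes (-0.071, padj = 0.000503). With row sets aligned the distances at 12.5 and 13.5 dpc were -0.075 and -0.069, and without dim genes -0.288 and -0.257. In supporting cells, where Xist was at 11.24, 11.32 and 11.24 in XX at the 3 stages, the distances were -0.004, -0.010 and -0.020 (padj = 0.695, 0.695 and 0.729). There 3, 37 and 37 X-linked genes were lower and 9, 53 and 52 higher.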

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

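The interaction tests and the splits of the arrays were planned, and the other tests of this part were chosen only after the result was seen. The sex difference of germ cells changed from 11.5 to 13.5 dpc in 281 genes, and that of supporting cells in 518. Both stood out because the difference between the stages was itself tested, by an interaction. In germ cells Stra8 (-4.88) and Nanos2 (3.82) were among the genes, in supporting cells Hsd17b3 (4.92) and Sry (-3.64, a lower bound of its size, since of the groups compared only XY cells at 11.5 dpc were above background). Of 100 splits of the 12 germ cell arrays 17 gave as many genes, with 3504 in the highest other. Of the 100 splits of the supporting cell arrays 10 did, with 1764 in the highest other. The arrays were shuffled within each stage, so a split can keep the sex difference of 1 stage whole. For this reason the splits cannot decide whether chance gave the counts, and chance is not excluded. Among the splits as large, 9 germ cell and 4 supporting cell splits moved most arrays of 1 stage to the other sex. Such a split moves the contrast toward the sum of the sex differences of both stages. A gene that differs at a single stage can pass it too. What made counts several times the real one in other splits was not tested. With row sets aligned the real counts were 943 and 1600, with 12 and 10 splits as large and 1485 and 3919 in the highest other.

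The other splits gave these counts. For germ minus supporting cells 1 of 100 splits, the real one, gave 8947 genes, and the highest other gave 1885. This argues against a chance division of these arrays, though 100 splits cannot give a smaller share and so cannot exclude it. If the arrays of a group are technical replicates, the splits test only the spread between arrays. Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. Between the sexes the real split and the highest other gave 5 and 0 genes in germ cells at 11.5 dpc, 775 and 111 at 12.5 dpc, 392 and 1 in supporting cells at 11.5 dpc, 2119 and 1 at 12.5 dpc, and 1947 and 0 at 13.5 dpc. Between the stages they gave 2390 and 0 in XX germ cells, 924 and 15 in XY germ cells, 560 and 0 in XX supporting cells, and 1188 and 0 in XY supporting cells. In each of these 1 split, the real one, was as large. For germ cells at 13.5 dpc 2 splits were as large, with 1275 genes in the real split and 5082 in the one that exchanges replicate 1 of the sexes. That split set array medians of 6.54, 6.76 and 6.62 against 6.98, 6.95 and 6.96, so it parted the arrays by level. With row sets aligned, which also centres the arrays, the highest other split gave 1 gene against 2671. Whether array level or row sets made the count was not tested apart.

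The array labelled germ XX 12.5 dpc replicate 3 lacked germ cell transcripts. Germ cells mixed with other cells are argued against by its germ cell identity median of 6.19, below the highest supporting cell array at 6.73, and a swap with another array used here by the 0 supporting cell arrays above the lowest other germ cell array. A wrong label, with XX somatic cells of stromal character on the array, is consistent with its interstitial or stromal median of 8.57, against 7.3 in the highest other array. Its pregranulosa median of 9.08 lay within the 8.16 to 9.51 of XX supporting cells, so whether it held stromal cells alone or with supporting cells stays open. The design gives no biological explanation, and none was tested.

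Each array held 2 or 3 interleaved row sets, at different levels in most arrays. The 6 supporting cell arrays at 11.5 dpc had distances of only 0.0 to 0.07 between their sets. Genes that differ in level between the sets are argued against by a median distance of 0.31 over all arrays that remains when each set is measured against the other arrays for the same probe sets. Alignment also scales and centres the arrays, so it was compared with scaling and centring each array as a whole. The median replicate SD was lower with row sets aligned in 10 of 12 groups, for example 0.098 against 0.246 in XY germ cells at 12.5 dpc. In supporting cells at 11.5 dpc it was not lower, at 0.111 against 0.11 in XX and 0.145 against 0.144 in XY. This is consistent with a rescaling of interleaved sets of rows during processing, at a step the sources used here do not describe. No biological explanation was tested.

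In supporting cells at 12.5 dpc sex coincides with reporter line and strain. Of the 2119 genes, 283 passed in the same direction at 11.5 dpc, where both sexes came from 1 line, against 21.3 if independent, and 4 in the opposite one, which argues against strain and line as the whole cause for the shared genes. Of the 1832 genes that passed only at 12.5 dpc, 78.3% lay in the same direction at 11.5 dpc, with a median of 0.25 in that direction. For these, sex, stage and strain or line cannot be told apart, since all 3 XY arrays at 12.5 dpc carry the other line. Of 5 genes tested as candidates for variation between strains (6 names, 2 of them for 1 gene) 0 passed limma (0 at an unadjusted p under 0.05, 0 with row sets aligned), which excludes nothing.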

How the results depend on the processing

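Row sets aligned, the removal of 1 array and both together were chosen after seeing the data; the other alternatives were planned. Counts had to stay within 1.5 times the reported one, and they did in all 13 comparisons with dim genes left out, with the mean over probe sets, and with a trended and robust prior. Among the printed and other named genes, leaving out 1 array at a time ended 562 calls and added 18 (8594 stayed), row sets aligned ended 30 and added 4 (719 stayed), array weights ended 42 and added 7, a fit of only the arrays compared 65 and 5, the trended prior 45 and 1, quantile normalisation 17 and 3, and centring 4 and 3. For the lists, an estimated correlation ended 71 calls (241 stayed), leave-one-out 41 with 23 added (3078 stayed), and row sets aligned 7 with 5 added (300 stayed). Signal near the background limits dim genes: without them the X-linked distance at 11.5 dpc in germ cells was -0.071. Unless said otherwise, the cause of a change below was not tested.

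Changed counts follow as sexes of germ cells by stage, sexes of supporting cells by stage, then stages in XX germ, XY germ, XX supporting and XY supporting cells, then the changes of the sex difference in germ and supporting cells. With row sets aligned they were 9 (germ 11.5), 2671 (germ 13.5), 1124, 4750 and 4324 (supporting), 2090 (XY germ), 1495, 3474, 943 and 1600, and the X-linked distance in germ cells at 11.5 dpc was -0.021, now past the test. With 1 array fewer besides, they were 20, 391, 3450, 1719, 5533, 5129, 4177, 2807, 2111, 4365, 1529 and 2341, and the distance -0.021. In the aligned values replicates lay closer together than in the deposited ones in every group, which lowers the errors. A fit of only the arrays compared gave 15 and 8 (germ 11.5 and 12.5), 614 and 4275 (supporting 11.5 and 13.5), 1296, 2751, 581 and 1687. Array weights gave 111 and 6461 (germ 12.5 and 13.5), 2162 and 6066 (supporting 11.5 and 13.5), 5203 (XX germ), 2713, 4768, 1612 and 3277. Quantile normalisation gave 1290 (germ 12.5) and 504 (germ change), and centring 1521 and 446. Autosomal genes only left 0 at germ 11.5, by construction.

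Stricter thresholds leave fewer genes by construction. At 2-fold or more there were 379 and 628 (germ 12.5 and 13.5), 1195 and 1127 (supporting 12.5 and 13.5), 1041, 520, 692 (XY supporting) and 2179 (germ minus supporting). At an adjusted p under 0.01 there were 204 and 704, 237 and 1397 (supporting 11.5 and 12.5), 1388, 529, 340, 708, 111 and 300. With an estimated correlation the X-linked distances of -0.141 and -0.116 in germ cells at 12.5 and 13.5 dpc were no longer past the test, the distances being the same, and without dim genes -0.071 at 11.5 dpc was past it.

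The direction reversed in germ cells at 12.5 dpc for Krt8 (0.07), germ cell identity (padj = 0.889), meiosis (padj = 1.66e-07) and the piRNA pathway (padj = 0.823) with row sets aligned and 1 array fewer, and for germ cell identity (padj = 0.991) and meiosis (padj = 0.00107) without the array labelled germ XX 12.5 dpc replicate 3, which held few germ cell transcripts. Leaving out 1 array at a time gave germ cell identity a lowest padj of 6.61e-11 (XX replicate 2) and a highest of 0.991 (XX replicate 3), and meiosis a lowest of 3.51e-06 (XX replicate 1) and a highest of 0.109 (XY replicate 3).

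Leaving out 1 array at a time, a group of 2 being assumed to vary like the others, gave the following lowest and highest counts, with the array left out. Germ cell sexes: 5 and 5 at 11.5 dpc, 179 (XY replicate 2) and 1936 (XX replicate 1) at 12.5 dpc, 696 (XX replicate 3) and 1914 (XY replicate 1) at 13.5 dpc. Supporting cell sexes: 249 (XY replicate 3) and 663 at 11.5 dpc, 1526 (XY replicate 1) and 2666 at 12.5 dpc, 1468 (XY replicate 3) and 2437 at 13.5 dpc. Stages: 1405 (13.5 dpc replicate 3) and 3050 in XX germ, 604 (11.5 dpc replicate 3) and 1416 in XY germ, 366 (13.5 dpc replicate 2) and 817 in XX supporting, 714 (13.5 dpc replicate 3) and 1768 in XY supporting cells. Germ minus supporting cells: 8653 (germ XY 13.5 dpc replicate 3) and 9508 (germ XY 13.5 dpc replicate 1). Changes of the sex difference: 159 (XX 13.5 dpc replicate 3) and 644 in germ, 376 (XX 13.5 dpc replicate 2) and 850 in supporting cells. Highest counts with no array named are without the array labelled germ XX 12.5 dpc replicate 3. None of these comparisons holds that array, so leaving it out moves no log2 difference in them. It changes only the errors, through the estimate of spread that all arrays share. X-linked distances in germ cells: -0.044 to -0.013 at 11.5 dpc (past the test without XX replicate 3, -0.032, and without XY replicate 3, -0.043), -0.153 to -0.117 at 12.5 dpc and -0.184 to -0.102 at 13.5 dpc. In supporting cells: -0.009 to 0.011, -0.026 to -0.010 and -0.028 to -0.013.

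The replicate number as a replicate block gave 5, 632, 1055, 355, 1884, 1720, 2299, 905, 509, 1135, 9190, 274 and 481 genes for the 13 comparisons, with germ minus supporting cells before the changes of the sex difference. Arrays of the same number in the groups compared correlated at -0.52 to 0.20, so the numbers were not treated as pairs. With the block 3 lists also passed: the piRNA list between the sexes of germ cells at 13.5 dpc (padj = 0.0364), the mitotic list between the stages in XX germ cells (padj = 0.0478) and the erythroid list between the sexes of supporting cells at 11.5 dpc (padj = 0.0125).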

Other observations

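Imprinted genes are expressed from 1 parental copy and often tied to growth. At 11.5 dpc 0 of 23 passed in germ cells (limma; 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 with row sets aligned; padj = 0.294). In supporting cells at 11.5 dpc 0 passed (limma; 2 at an unadjusted p under 0.05, 0 adjusted over the list alone, 2 with row sets aligned; padj = 0.982). There at 12.5 dpc 9 were lower in XY (9 adjusted over the list alone; padj = 8.48e-06, adjusted p = 0.193 with an estimated correlation), with Zim1 at -3.53 (SE 0.55) and the growth factor gene Igf2 at -2.90 (SE 0.46). At 13.5 dpc 7 were lower (9 adjusted over the list alone; padj = 7.21e-06, adjusted p = 0.188 with an estimated correlation), with Peg3 at -2.43 (SE 0.23). Both stages coincide with reporter line and strain, as does the fall of 5 imprinted genes in XY supporting cells from 11.5 to 13.5 dpc (5 adjusted over the list alone; padj = 7.05e-07, adjusted p = 0.285 with an estimated correlation). In germ cells at 12.5 dpc 12 were lower and Usp29 (0.85) was higher (17 and 1 adjusted over the list alone; padj = 1.33e-10, adjusted p = 0.0704 with an estimated correlation), and without the array labelled XX replicate 3 there were 4 lower (padj = 1.94e-06, adjusted p = 0.168 with an estimated correlation), Phlda2 at -3.0 and Plagl1 at -1.56 among them. At 13.5 dpc 3 were lower in XY germ cells, Phlda2, Plagl1 (-1.86) and Slc38a4 (-1.67), and Mest (1.57) was higher (4 and 1 adjusted over the list alone; padj = 0.0474, adjusted p = 0.771 with an estimated correlation). That list call was lost with arrays centred (padj = 0.0743) and without XX replicate 1 (padj = 0.069) or 2 (padj = 0.0511) or XY replicate 2 (padj = 0.0517) or 3 (padj = 0.084). In germ cells at 12.5 dpc, with row sets aligned and the array labelled XX replicate 3 left out, 7 imprinted genes were lower. Camera with an estimated correlation then gave an adjusted p of 4.57e-05. In XY germ cells 4 fell from 11.5 to 13.5 dpc (5 adjusted over the list alone; padj = 0.00367, adjusted p = 0.585 with an estimated correlation). Germ cells had 12 lower and 4 higher than supporting cells (12 and 5 adjusted over the list alone; padj = 3.33e-05, adjusted p = 0.162 with an estimated correlation).

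A list of 9 measured genes, inhibitors of cyclin-dependent kinases and others that hold the cell cycle, lay higher at 13.5 than at 11.5 dpc in XY germ cells. There 2 of them, Ccng2 (1.54, SE 0.27) and Rb1 (1.47, SE 0.35), neither such an inhibitor, rose (3 adjusted over the list alone; padj = 5.36e-05, and 0.0107 with an estimated correlation). In XX cells Ccng2 (1.16, SE 0.27), Cdkn2a (0.85, SE 0.18) and Cdkn2c (0.65, SE 0.19) rose (5 adjusted over the list alone; padj = 0.00457, adjusted p = 0.0567 with an estimated correlation). Dissociation stress genes, induced when tissue is taken apart, were lower in germ than in supporting cells in 11 of 14, Jun at -2.88 (SE 0.21) (11 adjusted over the list alone; padj = 1.78e-07, adjusted p = 0.13 with an estimated correlation). In XY supporting cells at 13.5 dpc 4 were lower and Nr4a1 (1.14) was higher than in XX cells (5 and 1 adjusted over the list alone; padj = 0.0261, adjusted p = 0.714 with an estimated correlation), with padj = 0.151 without XX replicate 3 and 0.0538 without XY replicate 1. Ier2 (0.99) rose in XX supporting cells (2 adjusted over the list alone; padj = 5.73e-05, adjusted p = 0.667 with an estimated correlation). In germ cells at 12.5 dpc 3 were lower in XY than in XX, Egr1, Fos and Junb (4 adjusted over the list alone; padj = 0.00105, adjusted p = 0.345 with an estimated correlation), and without the array labelled XX replicate 3 padj was 0.996. From 11.5 to 13.5 dpc Ier2 (-0.87) and Zfp36 (-1.04) fell in XX germ cells (2 adjusted over the list alone; padj = 0.0475, adjusted p = 0.81 with an estimated correlation). That call was lost with arrays centred (padj = 0.0518) and without 11.5 dpc replicate 2 (padj = 0.202) or 13.5 dpc replicate 1 (padj = 0.223) or 3 (padj = 0.0766). In XY germ cells the list lay lower at 13.5 dpc with 0 past limma (3 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 with row sets aligned; padj = 0.0261, adjusted p = 0.682 with an estimated correlation). It was lost with row sets aligned (padj = 0.121) and without 11.5 dpc replicate 1 (padj = 0.061) or 3 (padj = 0.0862) or 13.5 dpc replicate 3 (padj = 0.123). The change of the sex difference in supporting cells was downward for the list with 0 past limma (4 at an unadjusted p under 0.05, 1 up and 2 down adjusted over the list alone, 2 with row sets aligned; padj = 0.0163, adjusted p = 0.839 with an estimated correlation). It was lost with row sets aligned (padj = 0.098) and without XX 11.5 dpc replicate 2 (padj = 0.0903), XY 11.5 dpc replicate 2 (padj = 0.0867) or XX 13.5 dpc replicate 3 (padj = 0.124). Differences in handling can therefore not be excluded where these groups are compared. Of 13 endothelial genes 4 were higher in germ cells, Pecam1, which germ cells also express, at 3.10 (SE 0.19) (2 adjusted over the list alone; padj = 0.564), of 13 macrophage genes Tyrobp at 0.78 (1 adjusted over the list alone; padj = 0.623), and of 7 erythroid genes 0 (limma; 0 at an unadjusted p under 0.05, 2 past the test with row sets aligned; padj = 0.545). In the mesonephric and epithelial list 4 of 11 were higher, Epcam at 3.05 (SE 0.18), and 3 lower, Krt8 at -1.68 (SE 0.11) (4 and 3 adjusted over the list alone; padj = 0.993, median -0.03, mean 0.33, test downward). The macrophage list lay lower at 13.5 than at 11.5 dpc in XX supporting cells, with 0 of 13 past limma (1 at an unadjusted p under 0.05, 1 adjusted over the list alone, 2 past the test with row sets aligned; padj = 0.008, adjusted p = 0.667 with an estimated correlation, and padj = 0.0531 without 11.5 dpc replicate 3), and in XY supporting cells Cx3cr1 (-0.69) fell (2 adjusted over the list alone; padj = 0.00847, adjusted p = 0.387 with an estimated correlation, and padj = 0.0507 without 11.5 dpc replicate 2). Of 5 candidates for variation between strains 1 was higher and 2 lower in germ than in supporting cells (1 and 2 adjusted over the list alone; padj = 0.545). Foxl2, chosen after its values were seen, stood at 6.21, 6.36 and 6.29 in XX and at 6.15, 6.61 and 6.22 in XY supporting cells at the 3 stages. All but the 6.61 lay below 6.37, the cutoff used for dim genes. Such values cannot show whether the gene differs between the sexes.

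The test of the X-linked genes in this part was chosen only after their shift was seen; the splits were planned. X-linked genes lay lower in XY than in XX germ cells at 12.5 and 13.5 dpc, beside Xist at 8.28 or lower in the XX germ cell arrays other than the one labelled 12.5 dpc replicate 3 (11.02), which is included in these distances. With an estimated correlation the X-linked set did not pass camera at either stage (padj = 0.927). The hypothesis is that XX germ cells carry 2 active X chromosomes. It needs a larger sex difference of X-linked genes in germ than in supporting cells. Averaged over the stages, the median of germ minus supporting sex differences was -0.032 for X-linked and 0.046 for autosomal genes (camera p = 0.0181, and 0.535 with an estimated correlation), or p = 0.0187 and 0.0654 with row sets aligned. Within germ cells the change from 11.5 to 13.5 dpc gave p = 0.00275, and 0.433 with an estimated correlation, or 0.00166 and 0.0163 with row sets aligned. The hypothesis stays open, since the result turns on the correlation assumed between genes. The genes are not independent replicates.

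For the X-linked distance the 10 splits of each comparison are too few for a share under 0.05. The real distance and the largest of the other splits were -0.019 and 0.029 in germ cells at 11.5 dpc (6 splits as large), -0.141 and 0.075 at 12.5 dpc (1), and -0.116 and 0.083 at 13.5 dpc (1). In supporting cells they were -0.004 and 0.023 (9), -0.010 and 0.021 (5), and -0.020 and 0.020 (1).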
